A study of Mus musculus with 5 samples.

How the data were processed

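Thymic dendritic cells from untreated mice (2 libraries) and from mice 4 days after total body irradiation (3 libraries) were compared. Per the labels' protocols, thymi of C57BL/6J mice aged 6 to 8 weeks were digested with DNase and collagenase and pooled, dendritic cells were sorted by fluorescence, and RNA was purified with a micro-scale column kit. Libraries came from a SMART-Seq v4 kit and were sequenced on an Illumina HiSeq, per the labels. The kit amplifies polyadenylated RNA by PCR and adds no molecular identifiers, so intervals and floors given here cover counting error only. Reads were aligned to mm10 with STAR 2.5.2a and assigned to genes with Subread featureCounts 1.6.0, and edgeR and limma were then used, per the submitters' processing notes. The deposited values are whole-number read counts per gene symbol, not normalised, per the labels and the values themselves. The annotation, the strand setting, the treatment of multiply mapped reads and the radiation dose are not stated in the sources used here. Overlapping, antisense and near-identical genes may therefore share reads. The treatment note gives 4 days before harvest but names the samples by another day, while titles and treatment tags give day 4, which was used.

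The table held 18051 genes, of which 1476 had no count in any library, and 0 columns of other samples. A spreadsheet had turned 23 symbols into dates. These genes held 0.221% of the counts, stayed in the library totals and tests, 7 of them passed the threshold, and none is named. Total counts ran from 7227000 to 8428589, where 1 count is 0.138 and 0.119 CPM, and a floor of 3 counts is 0.356 to 0.415 CPM by total counts. Coordinates and gene models came from a GRCm38 annotation, matched by symbol.

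Counts were tested with edgeR 4.0.16 in R 4.3.3: TMM normalization, filterByExpr on the group (minimum count 10, minimum total 15), the quasi-likelihood F-test with robust = FALSE and Benjamini-Hochberg adjustment over 12046 genes at 0.05. The group was the only term. CPM values use TMM-scaled library sizes. Log2 fold changes are TBI minus untreated with their standard errors, and values after a gene's name in parentheses are these. Where every library of a group was at 0 counts, the fold is a bound against 3 counts per library. Where a group held 1 to 3 counts, the ratio has a 95% exact binomial counting interval. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

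The test, the settings, the rule for named genes and 36 gene lists were fixed before the data were examined. Named genes were the 12 largest rises and 12 largest falls past the threshold with a mean log2 CPM of at least 4 and no overlap of groups, leaving out predicted genes and antigen receptor segments, up to 4 members per list with the smallest p, or the 2 most expressed members where none passed, and 12 genes fixed by name (Il23a, Il12b, Nod2, Ripk2, Mertk, Axl, Tyro3, Rac1, Flt3, Zbtb46, Cdkn1a and Mdm2). Members named because 5 or fewer of a list moved in a direction, or as members that did not pass, were chosen after their values were seen. Lists covered cell types of the thymus and pathways of damage, uptake, signalling and metabolism, written from textbook knowledge. Of these, 34 had at least 3 tested members and were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01 between genes. In all 22 passed, 15 up and 7 down, and 0 passed when the correlation was estimated per list, where the lowest adjusted p was 0.220 and 7 had an unadjusted p under 0.05. In that setting camera also uses the residual degrees of freedom of the 5 libraries, so p rose even without correlation. The cytokine list, with an estimated correlation of -0.00347, went from an unadjusted camera p of 4.29e-05 to 0.0194. Calls lost in that setting therefore do not measure correlation alone. fry called 24. fry tests whether a list's genes move one way on balance and does not compare them with other genes.

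Alternatives were DESeq2 size factors, upper quartile scaling, library size alone, no filter on low counts, a stricter filter (1 CPM in 3 libraries and a total of 100 counts), a threshold of at least 2-fold, the DESeq2 1.42.0 Wald test, limma-voom, robust shrinkage, the replicate number as a block, and each library left out in turn. List tests were repeated with an estimated correlation, fry, voom weights and the main alternative scalings. With an untreated library left out, the lone untreated library is assumed to vary like the TBI libraries, and the genes tested stay those of the full set. Added after the data were seen were limma-voom with a variance per group and the removal of trends with GC content and transcript length in each library, for which 11981 tested genes (99.5%) had values. Functions were tested on simulated data with each gene's mean over all libraries, a single spread per gene for both groups and these library sizes. In these data 11789 genes were tested. Of simulated changes in this comparison, edgeR recovered 40% of 2-fold and 88.4% of 4-fold ones, with 4 false among 128 calls and 0 calls where nothing changed. limma-voom recovered 38% and 89.5%, and DESeq2 53% and 93.7% with 32 false among 174 calls. A simulated list of 20 genes raised 2-fold gave a camera adjusted p of 1.39e-23, and 0 of 30 unchanged lists were called. Simulated genes varied independently of one another, so this cannot test the preset correlation. In the data the estimated correlation was, for example, 0.897 for the ribosomal list, 0.220 for the macrophage list and -0.00347 for the cytokine list. The erythroid and mitochondrially encoded lists were left out of the tests for want of tested members. The result of 1 tested pathway list and some members that the rule for named genes selects are not reported here.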

Results

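RNA from dendritic cells of the mouse thymus was profiled in 5 libraries. Dendritic cells present antigen to developing T cells and take part in their negative selection. Untreated C57BL/6J mice gave 2 libraries, and mice harvested 4 days after total body irradiation (TBI) gave 3. Cells had been sorted as positive for CD45, MHC class II and CD11c. The libraries held 7346330 and 7227000 counts in the untreated group and 7549053, 8428589 and 7940442 counts in the TBI group, with 14621 and 14661 genes detected against 13679, 13786 and 14232. At this depth 1 count equalled 0.119 to 0.138 CPM. Groups lay farther apart than replicates: the chi-square per gene, which is 1 for pure counting error, was 5.11 between the untreated libraries, 10.1 to 29.2 between TBI libraries and 123 to 138 between groups. The first principal component separated the groups and held 72.7% of the variance. TBI replicate 1 stood apart from the other TBI libraries on the second component, which held 14.9%, with a score of -48.8 against 34.5 and 21.6. The labels describe pooled thymi and do not say that replicates came from separate pools, so adjusted p-values measure the spread between these samples.

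The comparison asks how the transcriptome of thymic dendritic cells differed 4 days after damage by irradiation. Saa3, Lyve1 and Ccl7 were among the largest rises, and Klk1, Cd207, Siglech and Havcr1 among the largest falls. Saa3, an acute-phase serum amyloid, went from 0.499 ± 0.168 to 649.5 ± 372 CPM (SD, n = 2 and n = 3), a log2 fold change of 10.30 ± 0.71 (SE; edgeR adjusted p = 2.94e-05). Lyve1, the hyaluronan receptor of lymphatic endothelium and of some tissue macrophages, went from 0.747 ± 0.341 to 188 ± 24.2 CPM (7.94 ± 0.29), and Ccl7, a monocyte chemoattractant, from 5.02 ± 2.03 to 814 ± 111 CPM (7.34 ± 0.29). Klk1, a kallikrein listed here as a plasmacytoid dendritic cell marker, fell from 282 ± 4.03 to 2.95 ± 0.887 CPM (-6.56 ± 0.22), Cd207, which encodes langerin, from 193 ± 36.2 to 4.43 ± 1.72 CPM (-5.44 ± 0.28), and Siglech, a plasmacytoid dendritic cell receptor, from 1077 ± 3.82 to 40.9 ± 23.8 CPM (-4.71 ± 0.46). Havcr1, which encodes the phosphatidylserine receptor TIM-1, fell from 386 and 334 counts to 0 counts in every TBI library, at least 112-fold lower against a floor of 3 counts per library. In GRCm38, the build also called mm10, Saa3 lies on chromosome 7, 46711998 to 46715700, Klk1 on chromosome 7, 44225360 to 44229618 and Havcr1 on chromosome 11, 46735080 to 46779578.

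Of 12046 genes tested with edgeR, 2778 (23.1%) passed an adjusted p of 0.05, 1599 higher and 1179 lower in the TBI libraries, and 1112 of the higher and 743 of the lower genes changed at least 2-fold. At an unadjusted p under 0.05 there were 4300. The groups did not overlap for 6759 genes (56.1%), where chance gives 20%. Median log2 fold change over all tested genes was -0.01, and scaling by library size alone moved it to -0.23. Under that scaling 36.8% of the called genes were higher, against 57.6% with TMM, and 2129 were lower. Without untreated replicate 1 there were 815 higher and 423 lower genes, without untreated replicate 2 there were 810 and 423, and without TBI replicate 1 the lower genes numbered 1780.

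Other genes among the 12 largest rises were Cd209f and Cd209g, C-type lectins of the DC-SIGN family, Folr2, a folate receptor of tissue macrophages, Prg4, which encodes lubricin, the B-cell chemokine Cxcl13, Ms4a8a, Gbp2b, Wnt2 and Kazald1. For those with 1 to 3 untreated counts in all, the count ratio with its 95% counting interval was 1519 (272 to 60026) for Cd209g, 439.8 (150.3 to 2135) for Ms4a8a, 580.0 (104 to 22935) for Gbp2b, 284 (78.4 to 2351) for Wnt2 and 397 (136 to 1929) for Cxcl13. Without the untreated library that held its counts, each of Cd209g, Gbp2b and Wnt2 was at 0 in the untreated group, and Cxcl13 had a log2 fold change of 7.71 without TBI replicate 1. Folr2 had 7.83 ± 0.33, Prg4 7.57 ± 0.46, Cd209f 8.15 ± 0.45 and Kazald1 7.57 ± 0.47. Leaving out untreated replicate 1 gave 8.85, 8.51 and 10.79 for Folr2, Prg4 and Cd209f, and leaving out untreated replicate 2 gave 8.50 for Kazald1. Other genes among the 12 largest falls were Mpo, Cd300c, Atp2a1, Cd209e, Klra17, Apol7c, Adam23 and Ccr9, a chemokine receptor of plasmacytoid dendritic cells and thymocytes. Cd300c (-5.17 ± 0.39), Atp2a1 (-5.15 ± 0.29) and Klra17 (-4.61 ± 0.20) moved by less than 1.5 times when any library was left out. Mpo, the myeloperoxidase of neutrophil precursors, had 67 and 872 untreated counts and 0 in every TBI library, at least 146-fold lower, or at least 20.6-fold without untreated replicate 2 and 275-fold without untreated replicate 1. Mpo was not called by limma-voom (adjusted p = 0.166), with robust shrinkage (0.0875) or by limma-voom with a variance per group (0.412). limma-voom did not call Cxcl13 either (adjusted p = 0.138). Reads of the Cd209, Klra and Apol7 families can be shared between near-identical copies, so values of single members are uncertain.

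Genes that mark type 1 and plasmacytoid dendritic cells mostly fell, and genes that mark type 2 dendritic cells moved both ways. Flt3, the receptor for the cytokine that maintains dendritic cells, fell from 328 ± 21.8 to 36.9 ± 4.01 CPM (-3.15 ± 0.15), Zbtb46, a transcription factor of conventional dendritic cells, from 53.6 ± 3.33 to 22.5 ± 2.82 CPM (-1.25 ± 0.19), and Irf8, a transcription factor needed for type 1 and plasmacytoid dendritic cells, from 1721 ± 53.2 to 427 ± 57.3 CPM (-2.01 ± 0.14). In the core dendritic cell list 8 of 14 members were lower, among them Bcl11a (-2.42 ± 0.29), 2 (Id2 and Nfil3) were higher and 4 did not pass. The core list had 2 higher and 8 lower adjusted over the list alone and a camera adjusted p = 0.00606, and adjusted p = 0.333 with an estimated correlation. Of 18 type 1 markers 16 were lower, 1 (Cd36) was higher and 1 (Batf3) did not pass, with a median log2 fold change of -2.0. The type 1 list had 2 higher and 16 lower adjusted over the list alone and a camera adjusted p = 2.63e-08, and adjusted p = 0.220 with an estimated correlation. The chemokine receptor Xcr1 (-2.84 ± 0.14), Gcsam (-2.37 ± 0.16) and the lysosomal thioesterase Ppt1 (-1.99 ± 0.14) were among them. All 14 called members of the 16 plasmacytoid markers were lower, with a median of -2.81, including Pacsin1 (-2.60 ± 0.19) and Smim5 (-3.46 ± 0.26), while Upb1 and Mzb1 did not pass. The plasmacytoid list had 0 higher and 14 lower adjusted over the list alone and a camera adjusted p = 1.67e-09, and adjusted p = 0.220 with an estimated correlation. Of 15 type 2 markers 7 were higher, 3 (Cd209d, Clec12a and Cd4) were lower and 5 did not pass. The type 2 list had 7 higher and 4 lower adjusted over the list alone and a camera adjusted p = 0.137. It passed with library size alone (adjusted p = 0.0484) and with fry (0.00599). Those that rose included the integrin Itgam (3.11 ± 0.24), the lectin Clec4a2 (2.59 ± 0.20) and the macrophage growth factor receptor Csf1r (2.23 ± 0.22), while Cd4 fell by 2.19 on the log2 scale. The 21 markers of CCR7-positive mature dendritic cells split into 5 higher and 6 lower. The CCR7 list had 5 higher and 6 lower adjusted over the list alone and a camera adjusted p = 0.779. The actin-binding Marcksl1 (1.25 ± 0.14) and Cd83 (0.71 ± 0.10) rose and the calcium channel subunit Cacnb3 (-2.27 ± 0.32) fell. In the same libraries 16 of 19 macrophage markers were higher and 11 of 23 immediate-early and dissociation stress genes were higher. Leaving out untreated replicate 1, the core list had 1 gene higher, the type 1 list 0 higher and the CCR7 list 2 higher and 2 lower, with its median at 0.16 instead of -0.07. The core list had 0 higher and 5 lower and the CCR7 list 2 higher and 4 lower without untreated replicate 2, and the CCR7 list had 3 higher without TBI replicate 2 and 2 higher with library size alone.

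**Figure D1:**
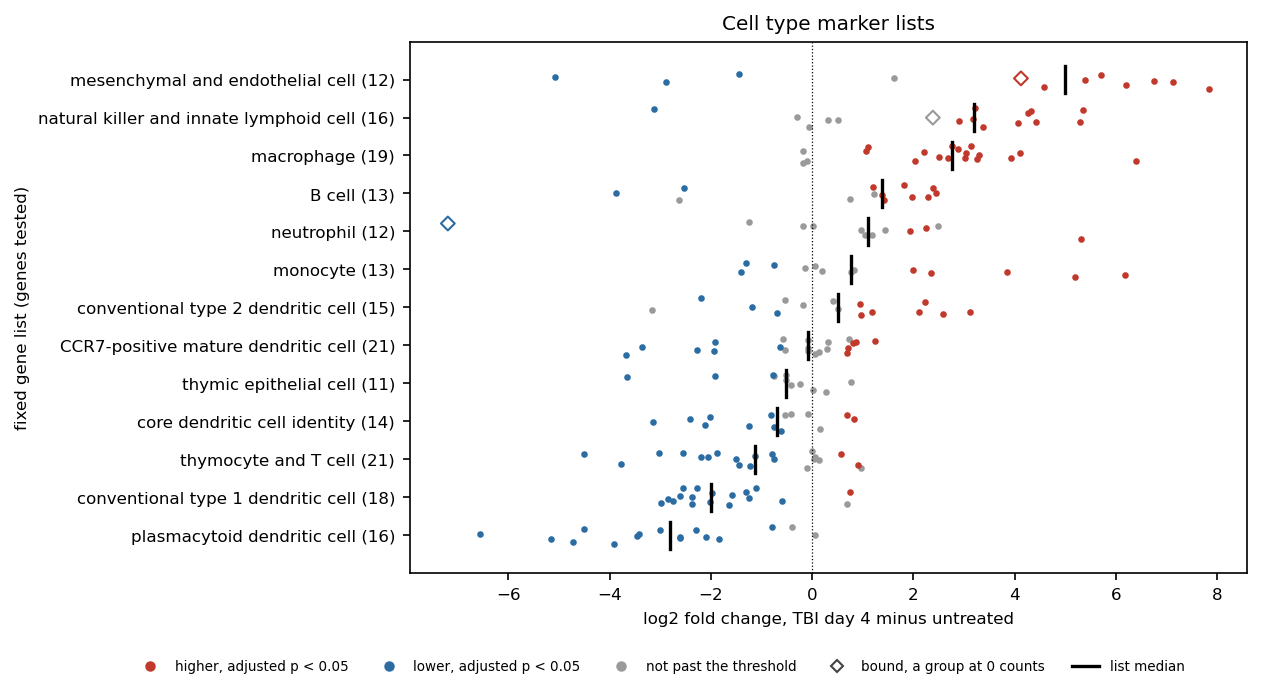
Log2 fold change, TBI day 4 minus untreated, of each tested member of the cell type lists, coloured red for higher, blue for lower and grey for not past the threshold; black bars are list medians and open diamonds are bounds for genes at 0 counts in a group. Macrophage members lie mostly above 0 (median 2.76) and plasmacytoid members mostly below 0 (median -2.81).

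Most macrophage markers rose. Cd14, a lipopolysaccharide co-receptor, went from 184 ± 18.4 to 3147 ± 505 CPM (4.10 ± 0.19), Apoe, a lipid carrier, from 1332 ± 208 to 11814 ± 1047 CPM (3.15 ± 0.15), Adgre1, which encodes the macrophage antigen F4/80, from 177 ± 4.75 to 1141 ± 48.3 CPM (2.68 ± 0.13), and the complement gene C1qb from 417 ± 81.6 to 3371 ± 13 CPM (3.01 ± 0.15). Of 19 macrophage markers 16 were higher, 0 were lower and 3 (Vcam1, Slc40a1 and Spic) did not pass, with a median of 2.76. The macrophage list had 16 higher and 0 lower adjusted over the list alone and a camera adjusted p = 3.12e-10, and adjusted p = 0.220 with an estimated correlation. Among 13 monocyte markers 5 were higher, 3 (Ly6c2, Plac8 and Treml4) were lower and 5 did not pass. The monocyte list had 5 higher and 3 lower adjusted over the list alone and a camera adjusted p = 0.0772. Lyz2, the myeloid lysozyme, went from 1922 ± 338 to 27629 ± 3936 CPM (3.85 ± 0.18) and its share of all counts from 0.238% and 0.184% to 2.91%, 2.54% and 2.31%. Fibronectin (Fn1, 6.19 ± 0.42), coagulation factor F13a1 (5.20 ± 0.31) and the chemokine receptor Ccr2 (1.99 ± 0.19) also rose. Without untreated replicate 1 or 2, 1 monocyte marker was lower instead of 3, and the monocyte list passed without untreated replicate 2 (adjusted p = 0.0344), with library size alone (0.0306), with voom weights (0.0411) and with fry (0.00311).

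Markers of lymphoid and stromal cells moved in different directions. A gate on CD45 is meant to remove stromal, endothelial and epithelial cells, although marker genes of such cells were counted in these libraries. Several natural killer cell genes rose, led by the granzymes Gzmb (9.58 ± 1.84 to 391 ± 47.3 CPM, 5.35 ± 0.21) and Gzma (4.07 ± 0.23), perforin (Prf1, 3.38 ± 0.29) and the receptor Cd226 (4.33 ± 0.33). Of 16 natural killer and innate lymphoid markers 10 were higher, 1 was lower and 5 did not pass, with a median of 3.30, or 3.20 with genes at 0 counts set to their bound. The natural killer list had 12 higher and 1 lower adjusted over the list alone and a camera adjusted p = 9.25e-06, and adjusted p = 0.220 with an estimated correlation. T cell genes mostly fell: 13 of 21 were lower, 2 (Cd2 and Cd3g) were higher and 6 did not pass, with 1 higher under upper quartile scaling or library size alone. The T cell list had 2 higher and 13 lower adjusted over the list alone and a camera adjusted p = 0.00145, and adjusted p = 0.237 with an estimated correlation. Cd8a (-2.54 ± 0.23), Cd8b1 (-2.06 ± 0.24) and the chromatin organiser Satb1 (-1.87 ± 0.22) were among those lower. Of the tested T cell markers 3 (Cd8a, Cd4 and Ccr9) are also on the dendritic cell lists. The T cell median was -1.12 with them and -0.77 without them. Of 13 B cell markers 8 were higher, including the antigen receptor components Cd79a (2.44 ± 0.29) and Cd79b (1.43 ± 0.19) and CD20 (Ms4a1, 2.39 ± 0.30), 2 (Cr2 and Fcrla) were lower and 3 did not pass. The B cell list had 10 higher and 3 lower adjusted over the list alone and a camera adjusted p = 0.00820, and adjusted p = 0.342 with an estimated correlation. Stromal collagen genes were at 0 or 1 count in each untreated library: Col3a1 had a count ratio of 284 (50.6 to 11228) and Col1a1 of 65.5 (11.5 to 2617). Of 12 mesenchymal and endothelial markers 8 were higher, 3 endothelial genes were lower (Cdh5, -5.08 ± 0.36, Pecam1, -1.44 ± 0.22, and Kdr) and 1 (Pdgfrb) did not pass, with a median of 5.55, or 4.99 with bounds. The mesenchymal and endothelial list had 8 higher and 3 lower adjusted over the list alone and a camera adjusted p = 0.0462, and adjusted p = 0.438 with an estimated correlation. Of 12 neutrophil markers 3 were higher, including the gelatinase Mmp9 (5.31 ± 0.32), 1 (Mpo) was lower and 8 did not pass. The neutrophil list had 4 higher and 1 lower adjusted over the list alone and a camera adjusted p = 0.0582. Of 11 thymic epithelial markers 3 were lower (Epcam, Dll4 and Ly75, the last at -1.91 ± 0.20), 0 were higher and 8 did not pass. Of these 11, 5 reached a mean of 10 CPM in untreated cells sorted for CD45, so the list need not track epithelial cells. The epithelial list had 0 higher and 3 lower adjusted over the list alone and a camera adjusted p = 0.0859. fry called it (adjusted p = 0.00651). Kdr (-2.89 ± 0.79) was not called by DESeq2 (adjusted p = 0.266) or without untreated replicate 1 (0.160) or 2 (0.0820) or TBI replicate 3 (0.0859), and its log2 fold change was -3.65 without TBI replicate 2. Dll4 was not called by DESeq2 (adjusted p = 0.121), nor Epcam without untreated replicate 1 (adjusted p = 0.199) or 2 (0.274) or TBI replicate 2 (0.0709) or 3 (0.0671), without the low-count filter (0.0511) or with the replicate block (0.113).

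Some of these counts moved when 1 library was left out. Leaving out an untreated library leaves 1 in that group and lowered the calls over all genes. Losses seen there alone do not show dependence on that library. Without untreated replicate 1 or untreated replicate 2, 1 B cell marker was lower, as it was without TBI replicate 2, and the higher neutrophil markers numbered 1 and 5. The higher T cell markers numbered 1 without untreated replicate 1, 0 without untreated replicate 2 and 1 without TBI replicate 3. Mesenchymal and endothelial markers had 5 higher without untreated replicate 2, 2 with limma-voom and 5 of 7 tested with the stricter filter. Their list did not pass without TBI replicate 1 (adjusted p = 0.114), without TBI replicate 3 (0.101), with fry (0.0726) or with voom weights (0.473). The neutrophil list passed without untreated replicate 2 (adjusted p = 7.28e-04), without TBI replicate 2 (0.0359), with library size alone (0.00896), with voom weights (0.0206) and with the replicate block (0.0478). Cd226 had a log2 fold change of 5.10 without untreated replicate 2, where Col3a1 and Col1a1 were at 0 counts in the untreated group.

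Many genes for the recognition and uptake of dying cells rose, and some fell. Pros1, the phosphatidylserine-binding ligand protein S, went from 14.6 ± 0.280 to 282 ± 43.4 CPM (4.27 ± 0.19), its receptor Mertk from 13 ± 1.55 to 53.2 ± 23.4 CPM (2.03 ± 0.38; adjusted p = 0.00618) and Axl, a receptor of the same family that binds the ligand Gas6, from 199 ± 20.8 to 430.3 ± 104 CPM (1.11 ± 0.21; adjusted p = 0.00629). Rac1, a small GTPase of actin remodelling, went from 608 ± 7.04 to 932 ± 58.9 CPM (0.62 ± 0.12; adjusted p = 0.00637). Tyro3, the other receptor of protein S in the family, had 4 and 0 counts against 13, 7 and 20, and its difference did not pass (adjusted p = 0.124). Of 27 genes for apoptotic cell recognition and uptake 16 were higher, 3 (Havcr1, Havcr2 and Cd300lf) were lower and 8 did not pass, with a median of 2.02. With the replicate block 5 were lower. The uptake list had 16 higher and 4 lower adjusted over the list alone and a camera adjusted p = 1.65e-04, and adjusted p = 0.354 with an estimated correlation. Of the listed genes 7 are also cell type markers, such as C1qa (2.88 ± 0.15) and C1qc (2.76 ± 0.15). Macrophage markers were higher in the same libraries (median 2.76). Axl was not called without untreated replicate 2 (adjusted p = 0.0623), nor Rac1 without untreated replicate 1 (0.0865) or 2 (0.0772), while Tyro3 was called by limma-voom with a variance per group (0.0437).

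Toll-like receptors moved both ways. Tlr2, which senses lipoproteins, went from 93.6 ± 11.8 to 374 ± 66.0 CPM (2.0 ± 0.19) and Tlr4, which senses lipopolysaccharide, from 6.63 ± 0.113 to 41.5 ± 10.6 CPM (2.64 ± 0.28), and Tlr11, which senses profilin, fell from 78.6 ± 5.32 to 15.2 ± 1.68 CPM (-2.37 ± 0.18). Of 29 innate pattern recognition genes 14 were higher, 2 (Tlr3 and Tlr11) were lower and 13 did not pass, with a median of 0.61. The pattern recognition list had 15 higher and 2 lower adjusted over the list alone and a camera adjusted p = 0.00135, and adjusted p = 0.314 with an estimated correlation. Of its genes 4 are also cell type markers, and macrophage markers were higher in the same libraries (16 of 19, median 2.76). Nod2, a cytosolic sensor of muramyl dipeptide, had 7.45 ± 1.45 to 6.38 ± 0.765 CPM (-0.22 ± 0.33; adjusted p = 0.673), and Ripk2, the kinase it signals through, 20.4 ± 1.06 to 27.7 ± 5.26 CPM (0.44 ± 0.23; adjusted p = 0.211), and neither passed. Without TBI replicate 1, Ripk2 was called (adjusted p = 0.0435). The list had 8 higher and 1 lower members without untreated replicate 2, and 1 lower without untreated replicate 1 or TBI replicate 2.

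Among secreted factors, Il12b, the subunit shared by interleukins 12 and 23, fell from 85.0 ± 47.4 to 6.58 ± 2.36 CPM (-3.68 ± 0.41; adjusted p = 3.76e-04), or -2.96 without untreated replicate 1. Il23a, the other subunit of interleukin 23, which drives interleukin 22 production by innate lymphoid cells, had 6 and 3 counts against 20, 50 and 3 (2.48 ± 1.11), and its difference did not pass (adjusted p = 0.149), although it was called without TBI replicate 3 (0.0360). Its log2 fold change was 1.5 without TBI replicate 2, and its adjusted p reached 0.491 without untreated replicate 2. The inflammatory cytokine Il6 rose from 11.3 ± 1.13 to 128 ± 20.9 CPM (3.50 ± 0.22), Bmp2, a bone morphogenetic protein, from 1.94 ± 0.652 to 50.1 ± 9.59 CPM (4.68 ± 0.33), and the growth factor Igf1 from 26.2 ± 4.06 to 112 ± 8.09 CPM (2.09 ± 0.18). Tgfb2 had 6 and 1 counts against 204, 310 and 219 (6.16 ± 0.49), or 7.83 without untreated replicate 1 and 5.42 without untreated replicate 2. Of 27 cytokines and growth factors 14 were higher, 3 (Il12a, Il12b and Hgf) were lower and 10 did not pass, with a median of 1.21. The cytokine list had 17 higher and 3 lower adjusted over the list alone and a camera adjusted p = 1.65e-04, and adjusted p = 0.220 with an estimated correlation. The monocyte chemoattractant Ccl2 rose from 7.12 ± 0.939 to 529 ± 94.6 CPM (6.21 ± 0.24), and Ccl8 (5.65 ± 0.25) and Ccl9 (5.29 ± 0.19) rose as well. Of 31 chemokines and receptors 17 were higher, 7 were lower and 7 did not pass, with a median of 0.83. The chemokine list had 19 higher and 8 lower adjusted over the list alone and a camera adjusted p = 1.81e-04, and adjusted p = 0.256 with an estimated correlation. Of the listed genes 10 are also cell type markers. Macrophage markers (16 of 19) and immediate-early and dissociation stress genes (11 of 23) were higher in the same libraries. The cytokine list had 9 higher and 1 lower members and the chemokine list 4 lower without untreated replicate 1, and the cytokine list had 1 lower without untreated replicate 2. Hgf and Il12a were not called without untreated replicate 1 (adjusted p = 0.189 and 0.204) or 2 (0.105 and 0.194), nor Il12a with the replicate block (0.0780).

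Some targets of p53, the transcription factor activated by DNA damage, rose. Cdkn1a, which encodes the cell cycle inhibitor p21, went from 150.3 ± 16 to 1035 ± 79.9 CPM (2.78 ± 0.15; adjusted p = 9.17e-06), Mdm2, the ligase that degrades p53, from 82.3 ± 3.97 to 272 ± 77.5 CPM (1.72 ± 0.25; adjusted p = 0.00159), and Phlda3 (4.26 ± 0.24), Gdf15 (3.31 ± 0.26) and Ccng1 (1.52 ± 0.16) were also higher. Of 29 p53 targets 13 were higher, 4 (Pmaip1, Trp53inp1, Sesn2 and Ccnd1) were lower and 12 did not pass, with a median of 0.75. The p53 list had 15 higher and 4 lower adjusted over the list alone and a camera adjusted p = 0.00810, and adjusted p = 0.220 with an estimated correlation. In the same libraries macrophage markers (16 of 19, median 2.76) and immediate-early and dissociation stress genes (11 of 23) were higher. BCL2 family and caspase genes had 8 of 25 higher, including the pro-apoptotic Bax (1.35 ± 0.17) and the survival gene Bcl2a1b (1.10 ± 0.16), whose reads can be shared with close copies, 4 (Bcl2l11, Bmf, Pmaip1 and Casp6) lower and 13 not past. The BCL2 list had 9 higher and 4 lower adjusted over the list alone and a camera adjusted p = 0.176. fry called the BCL2 list (adjusted p = 0.0128). The p53 list had 9 higher and 2 lower members and the BCL2 list 3 higher and 0 lower without untreated replicate 1. Without untreated replicate 2 they had 8 higher and 1 lower and 2 higher and 1 lower, and without TBI replicate 2 the BCL2 list had 2 lower. Casp6 was not called without untreated replicate 1 (adjusted p = 0.107).

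The number of cell cycle and DNA repair genes past the threshold depended on the setting. Of 26 mitosis genes 4 (Mki67, Cenpe, Cenpf and Prc1) were lower, with Mki67, a proliferation marker, at -0.77 ± 0.19 and Prc1, a spindle protein, at -0.89 ± 0.19, 0 were higher and 22 did not pass, with a median of -0.30. The mitosis list had 0 higher and 3 lower adjusted over the list alone and a camera adjusted p = 0.0162, and adjusted p = 0.436 with an estimated correlation. Of 30 DNA replication genes 3 (Dut, Gins2 and Cdt1) were higher, 0 were lower and 27 did not pass, with a median of 0.38. The replication list had 0 higher and 0 lower adjusted over the list alone and a camera adjusted p = 0.00135, and adjusted p = 0.314 with an estimated correlation. Dut, a nucleotide hydrolase, was at 0.75 ± 0.22. Of 30 DNA repair genes 2 (Chek1 and Xrcc5) were higher and 2 (Lig4 and Fanca) were lower. The repair list had 2 higher and 2 lower adjusted over the list alone and a camera adjusted p = 0.95. Chek1, a checkpoint kinase, was at 1.14 ± 0.27 and Lig4, a ligase of end joining, at -2.27 ± 0.45. The repair list had a median of 0.03, a mean of -0.05 and a camera direction of lower, and its median was -0.19 with library size alone, -0.01 with upper quartile scaling and -0.16 with the replicate block. No mitosis, replication or repair gene kept its call without untreated replicate 1, and the only repair gene called without untreated replicate 2 was Lig4, with no mitosis or replication gene called. Without TBI replicate 1, 8 mitosis genes were lower and 8 replication genes higher, and without TBI replicate 2 or 3, 2 mitosis genes were lower. With library size alone 9 mitosis and 4 repair genes were lower. Replication genes numbered 1 higher without TBI replicate 3 and 0 with upper quartile scaling or library size alone, but 5 with DESeq2, 5 with GC and length trends removed and 10 with a variance per group. Mitosis genes lower numbered 2 with the replicate block and 7 with a variance per group. With GC and length trends removed, edgeR no longer called Mki67 (adjusted p = 0.236), Cenpe (0.100), Cenpf (0.255), Dut (0.0683) or Cdt1 (0.0911). Across tested genes, log2 fold change had a Spearman correlation of -0.258 with log2 transcript length. The mitosis list did not pass with fry (adjusted p = 0.0650) or without TBI replicate 2 (0.0927), and 1 repair gene was lower without TBI replicate 2.

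Antigen presentation genes moved in both directions. Ciita, the activator of MHC class II genes, fell from 206 ± 7.08 to 68.8 ± 13.9 CPM (-1.58 ± 0.18) and H2-Oa, a class II chaperone, from 105 ± 3.77 to 32.4 ± 12.6 CPM (-1.70 ± 0.27), and the lysosomal proteases Lgmn (1.96 ± 0.18) and Ctss (1.22 ± 0.12) rose. Of 15 class II genes 2 were higher, 7 were lower and 6 did not pass. The class II list had 2 higher and 7 lower adjusted over the list alone and a camera adjusted p = 0.0994. Cd74, the class II invariant chain, took 3.10% and 3.04% of untreated counts and 2.93%, 2.26% and 2.14% of TBI counts, and did not pass (-0.10 ± 0.15; adjusted p = 0.674). Cd74 was called lower without TBI replicate 1 (-0.27, adjusted p = 0.0276) and with GC and length trends removed (-0.50, adjusted p = 0.00535), and had a log2 fold change of 0.0110 without TBI replicate 3 (adjusted p = 0.960). Of 17 class I genes 6 were lower, including the immunoproteasome subunit Psmb9 (-1.15 ± 0.13) and the peptide transporter Tap1 (-0.88 ± 0.13), 2 (H2-K1 and H2-D1, the latter at 0.62 ± 0.10) were higher and 9 did not pass. The class I list had 2 higher and 7 lower adjusted over the list alone and a camera adjusted p = 0.0489, and adjusted p = 0.436 with an estimated correlation. Interferon-response genes split, with Rtp4 (2.07 ± 0.17), the chemokine Cxcl10 (1.79 ± 0.17) and Ifi27l2a (1.56 ± 0.18) higher and Ifi44 (-1.36 ± 0.18) lower. Of 30 interferon-response genes 11 were higher, 5 were lower and 14 did not pass, with a median of 0.56. The interferon list had 12 higher and 6 lower adjusted over the list alone and a camera adjusted p = 0.0582. The interferon list passed without untreated replicate 1 (adjusted p = 0.0316), without TBI replicate 1 (0.0257), with fry (0.0400), with voom weights (0.0356) and with library size alone (0.0249). The class I list did not pass without untreated replicate 1 (adjusted p = 0.0902), without TBI replicate 2 (0.0948), without TBI replicate 3 (0.0907) or with the replicate block (0.125), and the class II list passed without TBI replicate 1 (0.0197) and with voom weights (0.0462). The class I, class II and interferon lists had 1 higher and 2 lower, 2 higher and 4 lower and 8 higher and 1 lower members without untreated replicate 1, and without untreated replicate 2 1 higher and 2 lower, 2 higher and 4 lower and 7 higher and 3 lower. With library size alone the class I list had 1 higher and 11 lower and the interferon list 11 higher and 8 lower with a median of 0.33, and with GC and length trends removed the class I list had 1 higher and 11 lower. In the same libraries plasmacytoid (14 of 16) and type 1 (16 of 18) dendritic cell markers were lower and macrophage markers (16 of 19) higher. Without TBI replicate 1, 11 genes were lower in each of the class I and class II lists, without TBI replicate 2 the class I list had 1 higher and 3 lower, and without TBI replicate 3 the interferon list had 3 lower.

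Many lipid-handling and lysosomal genes rose. Lipoprotein lipase (Lpl) went from 48.5 ± 6.16 to 816 ± 45.9 CPM (4.07 ± 0.16), the phospholipid transfer protein Pltp from 390.0 ± 11.2 to 2794 ± 141 CPM (2.84 ± 0.12), and Gpnmb, a glycoprotein of lipid-laden macrophages, from 13.9 ± 1.89 to 141 ± 36.1 CPM (3.35 ± 0.27). Of 22 LXR targets and lipid-handling genes 13 were higher, 0 were lower and 9 did not pass, with a median of 0.85. The LXR list had 13 higher and 1 lower adjusted over the list alone and a camera adjusted p = 6.35e-05, and adjusted p = 0.220 with an estimated correlation. The protease Ctsd (2.24 ± 0.12) and the membrane proteins Lamp1 (1.6 ± 0.12) and Lamp2 (1.37 ± 0.12) were among 19 higher lysosome and phagosome genes of 32, where 1 (Ctsl) was lower and 12 did not pass. The lysosome list had 23 higher and 3 lower adjusted over the list alone and a camera adjusted p = 3.72e-07, and adjusted p = 0.220 with an estimated correlation. Macrophage markers were higher in the same libraries (median 2.76). Without TBI replicate 1 the LXR list had 1 lower, with library size alone the LXR and lysosome lists had 10 higher and 2 lower and 18 higher and 3 lower, and without untreated replicate 2 the lysosome list had 0 lower.

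Cholesterol synthesis genes moved both ways, with the regulator Srebf2 (-1.02 ± 0.14) and the epoxidase Sqle (-1.33 ± 0.20) lower. Of 20 genes 6 were lower, 3, among them Mvd, were higher and 11 did not pass, with a median of -0.55. The cholesterol list had 3 higher and 7 lower adjusted over the list alone and a camera adjusted p = 0.0268, and adjusted p = 0.339 with an estimated correlation. Unfolded protein and integrated stress genes had 3 of 19 higher (Cebpb, 2.97 ± 0.15, Atf4 and Ppp1r15a), 7 lower, including the degradation component Herpud1 (-1.23 ± 0.15) and the asparagine synthetase Asns (-2.34 ± 0.41), and 9 not past. The unfolded protein list had 5 higher and 7 lower adjusted over the list alone and a camera adjusted p = 0.418. Glycolysis genes had 5 of 21 higher, including hexokinase Hk3 (1.48 ± 0.25), 2 (Slc2a3 and Ldhb, the latter at -2.35 ± 0.17) lower and 14 not past. The glycolysis list had 8 higher and 3 lower adjusted over the list alone and a camera adjusted p = 0.0926. The cholesterol list did not pass without untreated replicate 2 (adjusted p = 0.0741) or TBI replicate 2 (0.0656), and the glycolysis list passed without TBI replicate 1 (0.0486) and with voom weights (0.0358). The cholesterol, unfolded protein and glycolysis lists had 0 higher and 3 lower, 1 higher and 6 lower and 1 higher and 2 lower members without untreated replicate 1, and without untreated replicate 2 1 higher and 3 lower, 2 higher and 2 lower and 2 higher and 1 lower. Without TBI replicate 1 the unfolded protein list had 5 higher and 8 lower and the glycolysis list 11 higher and 2 lower, and the glycolysis list had 2 higher and 3 lower without TBI replicate 2, 2 higher and 3 lower with library size alone and 9 higher and 3 lower with a variance per group. Atf4 was not called without untreated replicate 1 (adjusted p = 0.0895), nor Slc2a3 without untreated replicate 2 (0.0657). In the same libraries macrophage markers (16 of 19) and immediate-early and dissociation stress genes (11 of 23) were higher. Type 1 (16 of 18) and plasmacytoid (14 of 16) dendritic cell markers were lower.

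**Figure D2:**
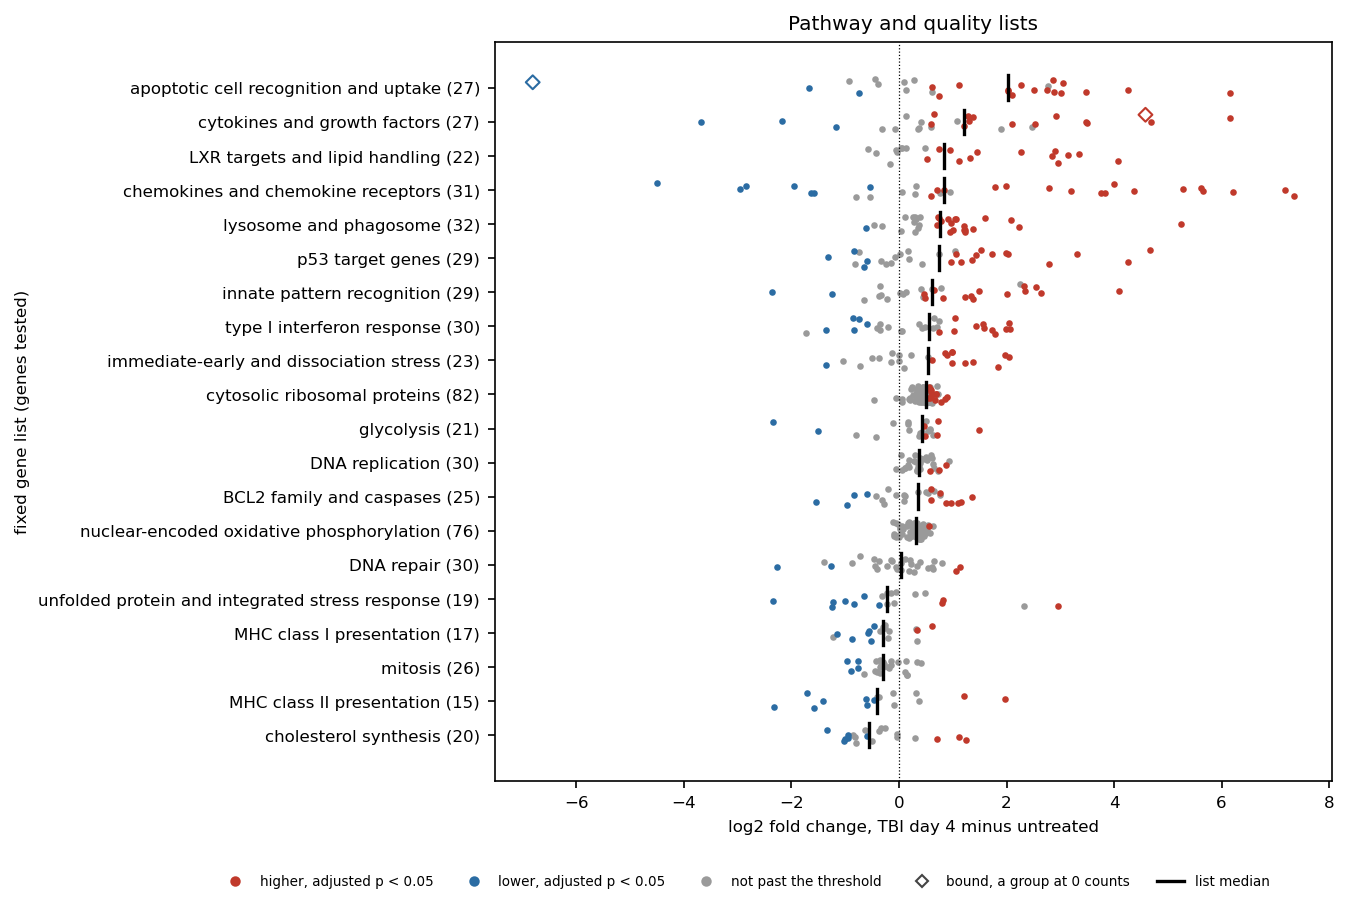
Log2 fold change, TBI day 4 minus untreated, of each tested member of the pathway lists, with the colours, bars and diamonds of the cell type plot. Lysosome and phagosome members lie mostly above 0 (median 0.77), and the DNA repair median of 0.03 is -0.19 with library size alone.

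The immediate-early genes Ier3 (2.05 ± 0.15), Dusp1 (1.98 ± 0.16), Egr2 (1.84 ± 0.17) and Junb (1.23 ± 0.13), which enzymatic dissociation can also induce, were higher. Of 23 such genes 11 were higher, 1 (Hsph1) was lower and 11, including Fos and Jun, did not pass, with a median of 0.55. The stress list had 11 higher and 2 lower adjusted over the list alone and a camera adjusted p = 0.00673, and adjusted p = 0.457 with an estimated correlation. It did not pass without untreated replicate 1 (adjusted p = 0.155). Lower members numbered 3 with library size alone, 4 without untreated replicate 1 and 0 without untreated replicate 2, TBI replicate 2 or TBI replicate 3. Of 82 ribosomal protein genes 13, such as Rps19 (0.89 ± 0.19) and Rpl12 (0.86 ± 0.20), were higher, 0 were lower and 69 did not pass, with a median of 0.50. The ribosomal list had 0 higher and 0 lower adjusted over the list alone and a camera adjusted p = 3.72e-07, and adjusted p = 0.516 with an estimated correlation. Of 76 nuclear-encoded oxidative phosphorylation genes 1 (Ndufa8, 0.57 ± 0.16) was higher, 0 were lower and 75 did not pass, with a median of 0.31. The oxidative phosphorylation list had 0 higher and 0 lower adjusted over the list alone and a camera adjusted p = 0.00194, and adjusted p = 0.647 with an estimated correlation. Neither list passed with fry (adjusted p = 0.153 and 0.320). Without untreated replicate 1 or 2 no gene of either list was called, and without TBI replicate 1, the library that stood apart, 35 ribosomal and 9 oxidative phosphorylation genes were higher. The higher ribosomal genes numbered 3 without TBI replicate 2, 23 without TBI replicate 3 and 2 with library size alone, and the higher oxidative phosphorylation genes 0, 7 and 0. With upper quartile scaling, DESeq2, the replicate block and a variance per group, the last added after the data were seen, 8, 25, 27 and 48 ribosomal and 0, 6, 7 and 11 oxidative phosphorylation genes were higher. With GC and length trends removed, a setting added after the data were seen, 2 ribosomal genes were higher and 1 was lower, and the oxidative phosphorylation median was -0.04. The erythroid list had 4 genes in the table, none of which was tested, and the mitochondrially encoded list had 0.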

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

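Chosen only after the data were seen were limma-voom with a variance per group and the removal of GC and length trends. In each setting every gene shared with the 2778 called ones kept its direction, for example 2420 shared with library size alone and 2764 with DESeq2. The count of changed genes stayed within 1.5 times across scalings, filters and tools, from 1855 with a 2-fold minimum to 3878 with a variance per group. Genes lower numbered 2129 with library size alone and 743 with a 2-fold minimum, the latter because fewer genes meet both conditions. Library size alone drops the TMM factors, which were 1.10 and 1.09 in untreated and 0.917, 0.937 and 0.964 in TBI libraries. Dropping them lowers log2 fold changes across genes, and the median over tested genes went from -0.01 to -0.23. Leaving out a library gave 1233 to 3928 changed genes, 810 to 2148 higher and 423 to 1780 lower, lowest without an untreated library, which leaves 1 in that group, and highest without TBI replicate 1. Of 22 lists past the threshold, 0 passed with the correlation estimated per list, against 22 to 26 in the other settings and 20 to 24 with a library left out. Estimating the correlation also changed the degrees of freedom of camera, so this loss is not due to correlation alone. Of 209 genes followed, 169 and 167 kept direction and call without untreated replicate 1 and 2, 193 to 201 without a TBI library and 195 to 208 in the other settings, and 194 of 194 kept both under the stricter filter. Where a sign turned, no call was involved: the CCR7 list without untreated replicate 1 (adjusted p = 0.785; 0.173 to 0.913 with a library left out), and the DNA repair list with fry (0.833), without TBI replicate 1 (0.970) and without TBI replicate 2 (0.715; 0.480 to 0.990 with a library left out). With a library left out, log2 fold changes ran from -0.90 to 0.0492 for Olr1, positive without TBI replicate 1, and from -0.27 to 0.0110 for Cd74, positive without TBI replicate 3 and called lower without TBI replicate 1 (adjusted p = 0.0276). For these the cause was not tested. The replicate block gave 2777 changed genes, 2353 of them shared, and 22 lists. Replicate 3 occurs only in the TBI group, so under the block that library adds nothing to the estimated group difference. The block thus overlaps with leaving out TBI replicate 3. The labels do not say that numbers pair libraries, and same-numbered libraries deviated with correlations of -0.016 and -0.010. In simulated data of this size 40% of 2-fold changes were recovered; other depths and numbers of libraries were not simulated.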

Other observations

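The serosal, alveolar, perivascular, mesothelial, adipocyte and progenitor lists and all genes in this part were chosen only after the values of the comparison were seen, as were the tests of library scaling, of GC and length trends on the macrophage and dendritic cell genes, of combined mesothelial counts and of a uniformly lower dendritic cell share. Some macrophage genes outside the fixed lists rose at day 4, with 6 of 8 tested serosal and 2 of 6 tested alveolar macrophage genes higher. All 6 tested perivascular and interstitial macrophage genes were higher. They included the mannose receptor Mrc1 (297 and 264 counts against 2482, 4355 and 4629, log2 fold change 3.85 ± 0.26), the haemoglobin scavenger receptor Cd163 (3.72 ± 0.39) and the selenium carrier Sepp1 (2.45 ± 0.17). Vsig4, a complement receptor, had 14 and 0 counts against 289, 846 and 661, and its log2 fold change was 6.46 ± 0.78, or 5.49 without untreated replicate 2, with 0 untreated counts when untreated replicate 1 was left out. Stromal genes differed widely between TBI libraries: decorin (Dcn) had 10 and 3 counts against 1290, 117 and 513, lumican (Lum) 2 and 0 against 310, 21 and 90, and the alarmin Il33 0 and 0 against 159, 6 and 37.

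Some granule genes of myeloid progenitors had most of their counts in untreated replicate 2. Counts were 67 and 872 for Mpo, 0 and 216 for the elastase Elane, 18 and 53 for cathepsin G (Ctsg) and 7 and 61 for Ms4a3, and all were 0 in each TBI library. Prtn3, of the same granules, had 1 and 59 counts against 83, 75 and 72 and did not pass, but was called higher without untreated replicate 2 (log2 fold change 6.20, adjusted p = 0.00185) and with a variance per group (0.0359). The progenitor list, which also holds genes of other functions, had 4 of 8 tested genes lower (Mpo, Ctsg, the surface protein gene Cd34 and the transcription factor gene Sox4). Cd34 had 239 and 249 untreated counts and Sox4 had 1314 and 960. Ctsg was not called without untreated replicate 2 (adjusted p = 0.0922) and Cd34 had an adjusted p of up to 0.222 with an untreated library or TBI replicate 2 left out. Of 6 adipocyte genes in the table none exceeded 58 counts in a TBI library, and 1 of 2 tested (Car3) was higher at an adjusted p of 0.0497. Car3 was not called under the 3 other scalings (0.0504 to 0.0640), without the low-count filter (0.0551), by limma-voom (0.109), with GC and length trends removed (0.0695), or without untreated replicate 1 (0.0778) or 2 (0.311) or TBI replicate 1 (0.0658) or 2 (0.117). Il22, an innate lymphoid cytokine, had 0 and 0 counts against 0, 23 and 21 and did not pass (edgeR adjusted p = 0.0833), but was called without TBI replicate 1 (0.00566).

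Several genes nearly absent from the untreated libraries were abundant at day 4, such as Saa3, Lyve1, Folr2 and Prg4, and macrophages that came with surrounding tissue are a candidate source. Of 7 mesothelial genes 6 were in the table and 0 reached the low-count filter, so a count of calls decides nothing. Combined mesothelial counts were 13 in the untreated libraries together and 10, 12 and 115 in the TBI libraries. They argued against mesothelial tissue as the source in TBI replicates 1 and 2, with 95% upper limits of 4.39 and 4.45 times. The highest rise, in TBI replicate 3, was 18.5 times (95% counting interval 10.4 to 35.8), under the smallest lower limit of the 12 largest rises, 78.4 for Wnt2. The most abundant, Upk3b, had 38 counts in TBI replicate 3 and 0 in the other TBI libraries. Much of the untreated background was Upk1b (3 and 4 counts), which lowers the ratio, so the comparison cannot decide for TBI replicate 3. Macrophages of the serosal cavities stay open, since 6 of 8 of their genes were higher, among them Alox15 (2535 and 2565 counts against 10128, 10790 and 9340) and Gata6 (2 and 0 counts against 60, 12 and 46; edgeR adjusted p = 0.0139), although 4 of the 8 exceeded 10 CPM in untreated thymus and Gata6 was not called without untreated replicate 2 (adjusted p = 0.0886) or by limma-voom (0.117). All 6 tested perivascular and interstitial macrophage genes were also higher (median 3.59), as were 16 of 19 macrophage markers. The serosal count therefore cannot single out this source. For alveolar macrophages the test could not decide, with a list median of 0.16 against 3.13 for the serosal list. Of 6 tested alveolar genes 2 were higher, Ear2 (101 and 87 counts against 1027, 577 and 623) and Atp6v0d2 (92 and 70 against 200, 382 and 278). Of the others, Siglecf (-0.62 ± 0.21), Car4 (-1.84 ± 1.07), Olr1 (-0.34 ± 0.47) and Plet1 (0.65 ± 0.48) did not pass, and Ear1 and Krt79 had at most 5 counts in any library. Siglecf was called lower in 7 other settings, for example with library size alone (adjusted p = 0.0256), and Car4 without TBI replicate 2 (-4.10, adjusted p = 0.0353). Plet1 was called higher without TBI replicate 3 (1.06, adjusted p = 0.0122) and with the replicate block (1.05, adjusted p = 0.0105), which would make 3 of 6. Siglecf was called lower in the same settings (adjusted p = 0.0345 and 0.0385). The gate on CD45, MHC class II and CD11c is meant to remove mesothelium but need not remove macrophages. Stromal genes such as decorin (10 and 3 counts against 1290, 117 and 513) were nonetheless counted, so the gate excludes neither source. A change of thymic macrophages after irradiation remains an untested biological explanation.

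Most macrophage markers were higher and most type 1 and plasmacytoid dendritic cell markers lower at day 4. Scaling and base composition were argued against: all 46 called members of these 3 lists kept direction and call under 3 other scalings, and 46 kept them with GC and length trends removed. The members were picked as called in the main fit, which favours this outcome. The largest move by a scaling, with library size alone, took the median of all tested genes to -0.23. A lower share of dendritic cells that raised every other cell type alike was tested on T cell genes in no other marker list. Their upper quartile of log2 fold change was 0.0595 (18 genes, median -0.77), below the macrophage lower quartile of 1.57. These genes did not rise alike, but a fall of T cells themselves would give the same values, so the test cannot decide. List medians were 3.30 for natural killer, 1.38 for B cell and 5.55 for mesenchymal and endothelial markers, against -0.52 for thymic epithelial markers. The epithelial list need not track epithelial cells in a CD45 gate. The pattern may reflect a changed makeup of the sorted cells, with fewer type 1 and plasmacytoid dendritic cells and more macrophages in the gate, or altered expression within cells. Bulk libraries do not separate these, and neither was tested here.

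Of 82 ribosomal protein genes 13 were called higher at day 4 and 0 adjusted over the list alone, with a list median of 0.50. The list passed with camera (adjusted p = 3.72e-07) but not with an estimated correlation (adjusted p = 0.516) or fry (0.153), and no member was called without untreated replicate 1 or 2. Trends with GC content and length may account for part of this: genes outside the list, matched to 80 of its members on length, GC content and mean expression, had a median log2 fold change of 0.26 against 0.49 for the list, or 52.2%, just over the bound set for this test. Variation of the whole set from library to library cannot be told apart from a group difference, since the lowest TBI library exceeded the highest untreated library by 0.193 in mean log2 CPM while the TBI libraries spanned 0.545. With the trends removed, which had been seen for the called genes before the matched test was run, 2 genes were called higher instead of 13, and with a variance per group 48 were. A change of translation capacity after irradiation remains an untested biological explanation.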
